A study of Mus musculus with 187 samples.

How the data were processed

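The series holds 187 MARS-seq plates of 384 wells from B16 melanoma mice, 71808 wells in all, and 3 tables that give a cell type for 27926 wells. Per the labels, plates were sorted by gate (CD45+, TCRB+ or CD11c+ MHCII+) from early tumors, late tumors and late draining lymph nodes, and 3 further plates held cells sorted as physically interacting or as their single-positive controls. Per the submitters' processing notes, bcl2fastq 2.15.0.4 and HISAT (version not given) were used with the mouse genome build mm10. The deposited plate files hold raw counts: whole numbers of molecules (UMIs) per gene and well for 52634 listed genes, not normalized. How the authors counted molecules, which annotation they used and how wells were filtered are not stated. The spike-in entries held 0 UMIs. Gene positions come from GENCODE vM21 (GRCm38, the same assembly as mm10) and are left out where a symbol had no single match.

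Each plate's gate, tissue and treatment were taken from the labels of each sample, its animal from the deposited tables, and each well's type from the deposited annotation. The treatment protocol in the labels describes injections of inactivated pathogens into the ear and an a41BB antibody, which match no group of this series, and was not used. Wells called Not_annotated there were left out. Wells of the type Not_Annotated (dLN) and of the type doublet (early tumors) stayed in the totals but were not tested. The animal was the unit of replication throughout: UMIs of the cells of a lineage were summed per animal, and cells of a type were counted per animal and gate. Lineages (CD8 T, CD4 T other than Treg, Treg, cDC1, monocyte and macrophage) were sums of the annotated types. Early CD4 types outside Treg still carried Foxp3. The gates, groups, tests, gene lists and naming rule were fixed before the data were examined.

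Depth was 40084 to 533694 UMIs per plate in early tumors, 150563 to 685185 in late tumors and 117154 to 435520 in the dLN. In the early CD45 gate 2205 (PBS), 3129 (PD1_Syn) and 3505 (PD1_Clec9a) wells were annotated, in the early TCRB gate 478, 639 and 414, and in the early CD11c+ MHCII+ gate 1116, 818 and 1428. In the late tumor TCRB gate 2062 (PBS), 812 (PD1) and 1960 (PD1_Clec9a) wells were annotated, in the late CD11c+ MHCII+ gate 938, 489 and 860, and in the dLN TCRB gate 2456, 1768 and 2594. The ability to find changes was checked on counts simulated from the data of each fit. In these counts 200 genes per fit were raised or lowered 2-fold or 4-fold. The share found is given for the comparisons simulated. For cell shares 50 simulations per gate used the same preset dispersion of 0.15 in each gate, not estimated from the data. The spread of the real shares may differ from it, so the percentages need not hold for them. A simulated 3-fold change was found in 73% of the simulated tests in the early CD45 gate. The values were 75% in the late TCRB gate and 80% in the dLN TCRB gate.

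Cell type shares were tested with the edgeR quasi-likelihood test on cell numbers per animal, with all annotated cells of the gate as library size, no TMM scaling, no abundance trend and no robust option. Benjamini-Hochberg adjustment ran over all types and the 3 contrasts of a gate, for types with at least 20 cells, over 7 gates. Genes were tested with edgeR 4.0.16 (R 4.3.3) on summed counts with TMM factors, filterByExpr and a robust quasi-likelihood fit of all 3 treatments, for animals with at least 20 cells of the lineage. Adjustment ran over the genes tested, and the threshold was an adjusted p of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. All tests were two-sided. The exact permutation test of cell type shares, used as an alternative, had little room to pass after adjustment at these group sizes. Its counts of 0 therefore decide little. In every contrast a positive log2 value means higher in the treatment named first. PD1_Clec9a was compared with the control antibody and with PBS. The control antibody was compared with PBS for shares in every gate, but for genes only in CD8 T cells.

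Of 24 gene lists, 12 were programmes: cytotoxic effector, checkpoint and exhaustion, naive, stem-like and memory T, proliferation, type I interferon response, interferon gamma response, MHC class I and class II presentation, Th1, regulatory T, dendritic cell maturation and suppressive macrophage. The others were a dissociation and heat shock stress list and markers of T, NK, B, cDC1, cDC2, plasmacytoid DC, monocyte and macrophage, neutrophil, mast, erythroid and melanoma cells. Lists with at least 4 tested genes were tested by limma 3.58.1 camera with a preset correlation of 0.01 and by fry, which tests whether a set's genes move on balance one way and does not compare the set with other genes. Adjustment ran over the programme lists within a contrast, and separately over the rest. Camera with an estimated correlation was the alternative. Of 152 programme tests 33 passed with the preset correlation and 5 with the estimated one: both interferon lists in dLN CD8 T and in dLN CD4 T cells against PD1, and MHC class I in those CD4 T cells. The interaction of tissue and treatment (PD1_Clec9a against PBS, late tumor and dLN) used 20 units, the tumor and the dLN of 10 mice, which the fit treated as independent. The pairing comes from the mouse ids of the deposited tables. The deviations of both tissues of a mouse from their group means correlated at -0.0344 to 0.105.

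Genes were named by a fixed rule: per comparison the 12 smallest p-values in each direction among those past the threshold, plus up to 10 programme list members past it, all of them where fewer than 10 passed, and Pdcd1 and Clec9a wherever tested. The text leaves out 1 gene that this rule names in dLN T cells. Cell types were named where they passed, and CD8 T, Treg, NK and cDC1 types in every case. List members named beside a list that did not pass over all genes were chosen after their values were seen. Shares of whole lineages were added after seeing the data and tested by exact two-sided permutation in scipy 1.17.1, with adjustment over the tests of a gate.

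For the plates of interacting cells, wells with at least 500 UMIs were thinned to 500 UMIs each, and the share of wells with any marker UMI was given with exact Clopper-Pearson intervals at 95%, which cover counting error only. A count of 0 is given with the limit that 3 counts allow, or the interval's upper bound. Genes were ranked by the ratio over the higher of both single-positive plates among those with at least 50 UMIs. Tables were handled in python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

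The results were recomputed with DESeq2 1.42.0 (Wald test), RLE factors, no filter on low counts, at least 10 or 50 cells per animal, cells with at least 500 UMIs, only the 2 treatments compared, the plate as the unit, T cells of the CD45 gate, TMM scaling or a permutation test for shares, leaving out a dLN plate whose gate label lacks a plus sign, leaving out each animal, and camera with an estimated correlation. Chosen after seeing the data were plate series as a term in early tumors, leaving out CD8 types that carry NK markers, unthinned sorted wells, gates limited to animals with at least 20 annotated cells, the animal as a block in the interaction, early CD4 T cells against PBS, and the alternatives of the lineage shares.

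Several planned comparisons could not be made in full. Early CD4 T cells with PD1_Clec9a against PBS had 1 animal in each arm, so the test there takes its spread from the PD1_Syn animals alone, and its alternatives were not run, other than at least 10 cells per animal. The early annotation had no NK type. In the dLN CD11c+ MHCII+ gate the annotation named only T cell types and covered 53 of 768 wells (PBS), 110 of 1536 (PD1) and 92 of 1920 (PD1_Clec9a), so cDC1 genes were not tested there. A batch term was not fitted for the dLN, since the undated dLN plates came only from PD1_Clec9a animals m14 and m15. None was fitted for late tumors either. There all PD1 plates carried higher plate numbers than most PD1_Clec9a plates, so plate order and treatment are hard to separate.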

Results

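Immune cells were sorted from mice bearing B16 melanoma, a transplanted mouse skin tumor, and their 3' ends were read by MARS-seq, a plate-based single-cell method that tags each RNA molecule. Per the treatment label of each sample, mice received a bispecific antibody binding PD1, the inhibitory receptor of activated T cells, and CLEC9A, a surface receptor of type 1 conventional dendritic cells (cDC1). This arm is called PD1_Clec9a below. Control mice received PBS, a bispecific with PD1 and Synagis arms (PD1_Syn, early harvest) or the PD1 antibody alone (PD1, late harvest). The 187 plates held 71808 wells, 57558162 molecules (UMIs) and 27926 wells with a deposited cell type. Plates held 40084 to 533694 UMIs in early tumors, 150563 to 685185 in late tumors and 117154 to 435520 in the late draining lymph nodes (dLN). An annotated well held a median of 1000 UMIs in early tumors, 1077 in late tumors and 872 in the dLN. Animals were the replicates: 4 PBS, 5 PD1_Syn and 5 PD1_Clec9a mice for early tumors, and 5 PBS, 3 PD1 and 5 PD1_Clec9a mice for late tumors and for the dLN T cell gate. Gene levels are UMIs of a gene scaled to the TMM-adjusted total of the animal's cells (CPM). Errors are SD across animals for shares and levels, and SE for log2 fold changes. Test results are two-sided edgeR quasi-likelihood p-values adjusted by Benjamini-Hochberg, unless another test is named.

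The first question was whether the bispecific antibody altered the immune make-up of early tumors relative to both controls. CD8 T cells took up more of the CD45+ cells in PD1_Clec9a tumors than in PD1_Syn tumors. Dysfunctional CD8 cells were 9.31% ± 5.61 (n = 5) against 2.2% ± 0.57 (n = 5), a log2 rise of 2.08 ± 0.48 (edgeR, adjusted p = 0.0170). Activated CD8 cells rose to 8.24% ± 3.24 from 3.13% ± 0.91 (log2 1.39 ± 0.34, edgeR, adjusted p = 0.0170). Eff CD8 cells were 4.64% ± 1.91 against 1.69% ± 0.94 (log2 1.40 ± 0.42), and Early Eff CD8 cells 1.93% ± 0.28 against 0.883% ± 0.347 (log2 1.11 ± 0.35, edgeR, adjusted p = 0.0431 for both). Naive Memory CD8 cells did not pass (log2 0.36, edgeR, adjusted p = 0.539). Against PBS, Dysfunctional CD8 (log2 1.61 ± 0.51, PBS 2.99% ± 2.20) and Activated CD4 cells (4.05% ± 1.98 against 1.42% ± 0.68, log2 1.52 ± 0.45, 4 of 5 animals above the PBS mean) rose (edgeR, adjusted p = 0.0431 for both). Activated CD8 cells stayed short of the threshold against PBS (log2 1.04, edgeR, adjusted p = 0.0656).

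Treg and cDC1 shares, by contrast, did not pass. Treg cells, the Foxp3-dependent suppressors of T cell responses, were 4.95% ± 3.53 of CD45+ cells with PD1_Clec9a, 2.56% ± 1.40 with PD1_Syn (log2 0.95, edgeR, adjusted p = 0.208) and 1.5% ± 0.91 with PBS (log2 1.73, edgeR, adjusted p = 0.0612). Xcr1+ Cadm1+ cDC, the cDC1 population that takes up dead cells and cross-presents their antigens, were 2.66% with PD1_Clec9a, 2.77% with PD1_Syn (log2 -0.09, edgeR, adjusted p = 0.841) and 4.70% with PBS (log2 -0.84, edgeR, adjusted p = 0.145). The early annotation named no NK type, but the cells called Naive Memory CD8 carried the NK genes Ncr1 and Klrb1c. In all, 6 of 54 tests of 18 types passed by edgeR, all of them higher with PD1_Clec9a and none between PD1_Syn and PBS, with 16 at an unadjusted p under 0.05.

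Limits on these 6 calls are set by single animals and by the size of the groups. Without m21 (PD1_Clec9a) or m23 (PD1_Syn) 0 tests passed. The count was 1 without m28, 2 without m14, m16, m18, m24 or m26, 3 without m31, 4 without m13, m17 or m25, 9 without m20 and 10 without m29. It was 2 with TMM scaling of the cell numbers, and 0 with an exact permutation test (11 at an unadjusted p under 0.05), whose smallest possible p was 0.00794.

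Summed over all CD8 types, a measure chosen after the data were seen, CD8 T cells were 25.8% ± 10.7 of CD45+ cells with PD1_Clec9a, 9.20% ± 1.77 with PD1_Syn and 12.4% ± 4.35 with PBS. All 5 PD1_Clec9a animals lay above all 5 PD1_Syn animals (exact two-sided permutation p = 0.00794, the smallest these groups allow). Adjusted over 21 lineage tests the value was 0.0833. Against PBS the exact permutation p was 0.0714, adjusted 0.214. Early plates fell into 3 plate series, and the PD1_Clec9a mean was higher in each: 30.4% against 9.09% (PD1_Syn) and 17.7% (PBS) in series A, 27.2% against 7.48% and 12.3% in series B, and 22.1% against 11% and 7.28% in series C. Every arm of series A and the PBS arm of series C was 1 animal, and the other arms were 2 animals each. Monocytes and macrophages were 50.4% ± 14.4 with PD1_Clec9a and 69.8% ± 5.64 with PD1_Syn (exact permutation p = 0.0397, adjusted 0.208).

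**Figure D1:**
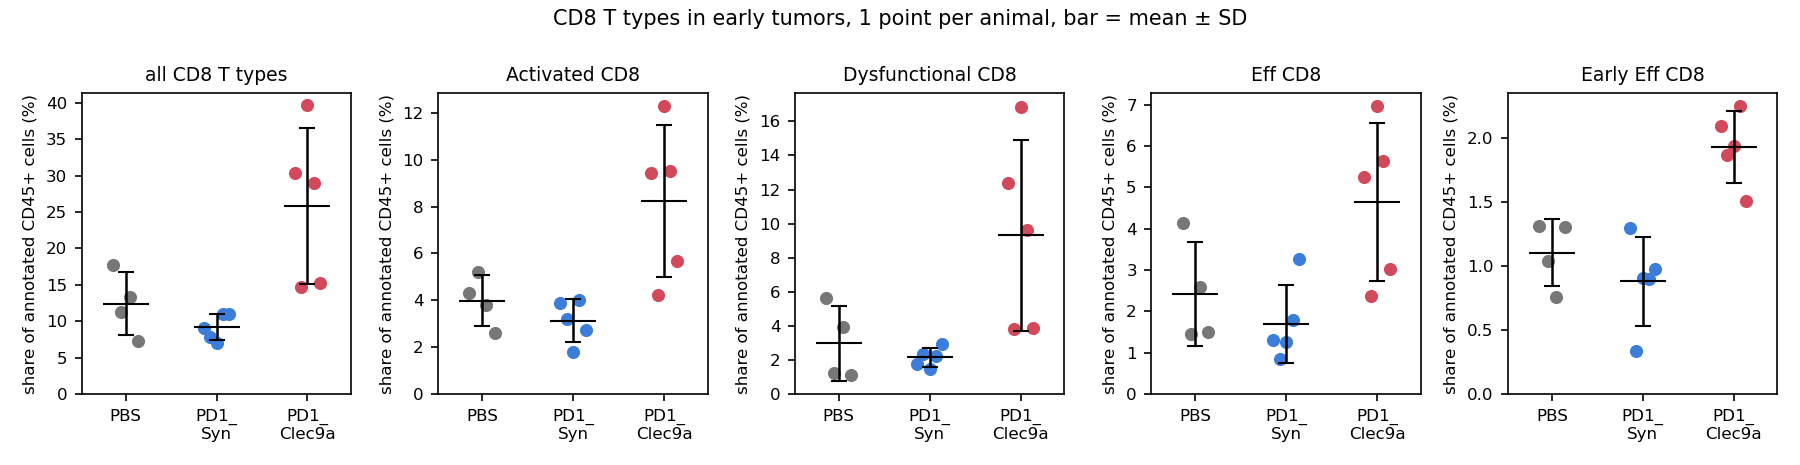
Share of annotated CD45+ cells (percent) taken by all CD8 T types and by 4 CD8 types in early tumors, 1 point per animal, bars for mean ± SD. All CD8 T types averaged 25.8% with PD1_Clec9a, 9.20% with PD1_Syn and 12.4% with PBS.

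Within the sorted T cells (TCRB gate) of early tumors, no type passed. CD8 T types made up 72.5% of annotated TCRB+ cells with PD1_Clec9a, 67.6% with PD1_Syn and 71.6% with PBS. Activated CD8 cells were 37.8% ± 9.06 (n = 4) against 24.1% ± 15.2 (n = 5) with PD1_Syn (log2 0.92, edgeR, adjusted p = 0.309), and Treg cells 12.2% against 15.1% (log2 -0.76, edgeR, adjusted p = 0.443). These means count PD1_Syn animal m26 (4 annotated cells) and PD1_Clec9a animal m29 (6 cells) as full animals. PD1_Clec9a animal m21, with the largest CD8 T share of the CD45 gate (39.6%), had no TCRB plate and is absent here. Among animals with at least 20 annotated cells, a limit chosen after seeing the data, the CD8 T share was 74.4% ± 4.70 with PD1_Clec9a (n = 3), 59.4% ± 12.2 with PD1_Syn (n = 4) and 71.6% ± 16.8 with PBS (n = 4), Activated CD8 cells were 33.7% and 17.6% with the 2 antibodies, and Treg cells 10.7% and 18.9%. By edgeR 0 of 24 tests passed with either set of animals, with 2 at an unadjusted p under 0.05. The count was 1 with TMM scaling, and 1 with plate series as a term, an alternative chosen after seeing the data. In the CD11c+ MHCII+ gate Xcr1+ Cadm1+ cDC were 15.8% with PD1_Clec9a, 11.3% with PD1_Syn and 11.1% with PBS (log2 0.48 and 0.50, edgeR, adjusted p = 0.846 for both). There 0 of 27 tests passed by edgeR, with 0 at an unadjusted p under 0.05. The permutation test also passed 0 in both gates, but groups of this size left it little room to pass after adjustment.

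Gene levels in CD8 T cells from early tumors differed between PD1_Clec9a (3 animals) and PD1_Syn (4 animals) in few genes. Of 2623 genes, 2 fell and 0 rose (184 at an unadjusted p under 0.05, 2 lower by DESeq2). Malat1, a long non-coding RNA retained in the nucleus (chromosome 19, 5795690 to 5802672, mm10), fell by 2.00 ± 0.29 on the log2 scale (105 ± 11.8 against 419 ± 121 CPM, edgeR, adjusted p = 1.57e-04, all 3 PD1_Clec9a animals below all 4). Gm26917, a lincRNA locus that can collect ribosomal RNA reads (chromosome 17, 39843013 to 39846341), fell by 0.99 ± 0.18 (edgeR, adjusted p = 0.0300). In the CD8 T cells of the CD45 gate, which include animal m21, neither passed (Malat1 log2 -0.48, edgeR, adjusted p = 0.834, and Gm26917 log2 -0.32). The Gm26917 call was lost without m16, m18, m20, m23, m24, m28 or m31. Pdcd1, the gene of PD1, was 626 ± 47.8 against 704 ± 83.0 CPM (log2 -0.18, edgeR, adjusted p = 0.906).

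None of the fixed gene programmes passed in early CD8 T cells. The inhibitory receptor Havcr2 (TIM-3) was the 1 checkpoint gene to pass when adjusted over the list alone (log2 -1.04), and 0 of that list passed over all genes. Against PBS 0 genes passed by edgeR (96 at an unadjusted p under 0.05, 0 by DESeq2), or 2 without m14, and between PD1_Syn and PBS 0 passed (165 at an unadjusted p under 0.05, 0 by DESeq2). Pdcd1 gave log2 -0.13 and 0.05 in these comparisons. Among 200 genes raised or lowered in counts simulated from the early CD8 T data, 36% of 2-fold and 84% of 4-fold changes were found, with 2449 genes tested.

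Early CD4 T cells other than Treg could be compared with PD1_Syn only through 1 PD1_Clec9a animal (m28) against 4, assuming that it varies like the others. Of 1779 genes 1 was called lower: Gzmb, the cytotoxic protease granzyme B, at 34.4 CPM in m28 against 669 ± 418 (log2 -4.02 ± 0.92, edgeR, adjusted p = 0.0201, with no spread measured in the PD1_Clec9a arm). Without m23 0 genes passed, and in CD45-gate cells the sign of Gzmb turned (log2 1.48, edgeR, adjusted p = 0.309). The count was 2 without m14 and 3 without m31. DESeq2 gave 1 lower gene, which was not Gzmb (adjusted p = 1.0). Pdcd1 gave log2 -0.59 (edgeR, adjusted p = 0.901). Here 110 genes had an unadjusted p under 0.05, and 51% of simulated 4-fold changes were found. Against PBS, with 1 animal in each arm and the spread of the PD1_Syn animals, 0 of 1779 genes passed by edgeR (82 at an unadjusted p under 0.05), and 0 of 629 among 3 and 2 animals with at least 10 cells (25), both tests chosen after seeing the data.

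The second question was what the antibody did to cells that carry its dendritic cell target. In early tumor cDC1, 2 of 1239 genes were lower than with PD1_Syn (5 against 4 animals), and both were lincRNA loci next to each other on chromosome 17 that can collect ribosomal RNA reads. Gm42418 (39846958 to 39848788) was lower by 1.11 ± 0.18 and Gm26917 by 1.02 ± 0.17 on the log2 scale (edgeR, adjusted p = 0.0010 for both, all 5 PD1_Clec9a animals below all 4). By group means PD1_Syn stood apart, but it was not tested against PBS in these cells. Gm42418 was 32809 CPM with PD1_Clec9a, 70491 with PD1_Syn and 26839 with PBS, and Gm26917 was 34542, 69759 and 34649. Neither passed for PD1_Clec9a against PBS (log2 0.29 and 0.00, edgeR, adjusted p = 0.997 for both). Clec9a, which encodes the antibody's target, was 500.1 ± 168 against 401 ± 128 CPM (log2 0.34, edgeR, adjusted p = 0.879) and log2 0.12 against PBS (edgeR, adjusted p = 0.997). DESeq2 gave 3 lower genes, and 97 had an unadjusted p under 0.05. The count was 4 without m23, m24 or m25.

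Proliferation genes fell as a list in early cDC1 against PD1_Syn (median log2 -0.68, camera adjusted p = 0.00179, but adjusted p = 0.306 with an estimated correlation). Mki67, a marker of cycling cells, had log2 -1.15. The list did not pass without m20 (median -0.48) or m23 (-0.38). The dissociation and heat shock stress list, a possible sign of handling, also fell (median log2 -0.18, camera adjusted p = 0.00746, and adjusted p = 0.0851 with an estimated correlation), with Hspa8 at -1.03 and Egr1 at -1.64. It did not pass without m14 (median -0.15), and its median was -0.32 without m23 and -0.28 without m29. Against PBS 0 genes passed by edgeR (49 at an unadjusted p under 0.05, 0 by DESeq2). The stress list fell there too, with 10 of 10 members lower (median log2 -0.34, camera adjusted p = 1.15e-04, adjusted p = 0.0185 with an estimated correlation). Atf3, a stress-induced transcription factor, had log2 -1.03.

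In early monocytes and macrophages 0 of 5370 genes passed by edgeR against PD1_Syn (216 at an unadjusted p under 0.05, 0 by DESeq2) and 0 against PBS (237 and 0). The MHC class II presentation list fell against PBS (median log2 -0.27, 8 of 9 members lower, camera adjusted p = 0.00108, but adjusted p = 0.396 with an estimated correlation). Its mean log2 CPM was 9.75 to 10.23 with PD1_Clec9a, 9.83 to 10.08 with PD1_Syn and 10.20 to 10.40 with PBS. The control antibody thus lay as low, and a fall particular to PD1_Clec9a was not shown. The proliferation list rose against PD1_Syn (median log2 0.13, camera adjusted p = 0.0433, but adjusted p = 0.605 with an estimated correlation). It did not pass without any 1 of m16, m18, m21, m23, m26, m28, m29 or m31 (medians 0.06 to 0.18), and its median was 0.31 without m14, 0.37 without m20 and 0.22 without m17 or m24. Markers of cDC2 fell against PBS (median log2 -0.17, camera adjusted p = 0.0257, adjusted p = 0.0975 with an estimated correlation). They did not pass without m16 (median -0.13) or m25 (-0.14), and the median was -0.32 without m21 and -0.30 without m24. The suppressive macrophage list did not pass in either comparison (smallest camera adjusted p 0.544). This fit found 71% of simulated 2-fold changes.

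At the late harvest the question was how CD8 T cells in the tumor differed between the bispecific and the PD1 antibody alone. With PD1_Clec9a (5 animals), Il7r and Slamf6 were higher and the granzyme genes Gzmb and Gzmc lower than with PD1 (3 animals). Of 5340 genes 36 rose and 12 fell. Il7r, the IL-7 receptor chain that keeps naive and memory T cells alive (chromosome 15, 9505788 to 9530176), rose by log2 1.92 ± 0.29 (232 ± 59.3 against 61.8 ± 19.3 CPM, edgeR, adjusted p = 2.97e-04). Slamf6, a surface receptor carried by progenitor-like T cells (chromosome 1, 171917515 to 171953170), rose by 1.87 ± 0.38 (139 ± 45.2 against 38.5 ± 12.9, edgeR, adjusted p = 0.0106). Gzmb (chromosome 14, 56258838 to 56262260) fell by 1.37 ± 0.21 (745 ± 221 against 1929 ± 132 CPM, edgeR, adjusted p = 2.97e-04). Gzmc, a neighbouring granzyme gene (56231441 to 56234656), fell by 3.17 ± 0.56 (22.1 ± 15.6 against 199.8 ± 77.6, edgeR, adjusted p = 0.0106). All 5 PD1_Clec9a animals lay on that side of the 3 PD1 animals for these 4 genes.

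Other named genes that rose were Thap3 (log2 2.37 ± 0.34, edgeR, adjusted p = 2.89e-04), the cofilin phosphatase Ssh2 (2.19), the G protein signalling regulator Rgs10 (2.80), the ubiquitin ligase adapter Klhl6 (2.08), the transporter chaperone Emb (1.52), the selenium carrier Selenop (3.58), Gm26740 (2.23), the transcription factor Klf3 (1.98) and the splicing kinase Clk1 (1.33). Animal m11 had the highest level of Ssh2 (553 CPM), Rgs10 (224), Klhl6 (329) and Emb (1444), and without it these passed at log2 1.71, 2.31, 1.64 and 1.15. The transcript 5730508B09Rik also rose, from 2.16 to 48.8 CPM, a level too near 0 with PD1 for a fold. Among those that fell were the glycolytic enzymes Ldha (log2 -0.74, 1585 against 2656 CPM) and Aldoa (-0.85), the mitochondrial chaperonin Hspd1 (-1.07), the proteasome subunit Psma4 (-1.10), the mitotic gene Cdca3 (-1.66), the metalloprotease Adam8 (-1.91), the chemokine Ccl1 (-3.42) and Anp32b-ps1 (-2.23). Few Ccl1 UMIs came from the PD1_Clec9a animals, so the size of its fold is uncertain. Mir147 (-2.36) and AA467197 (-2.61) fell as well. Mir147 lies inside AA467197 on chromosome 2, so it is uncertain which of them their reads belong to. Pdcd1 was 457 ± 94.2 against 572 ± 35.3 CPM (log2 -0.33, edgeR, adjusted p = 0.461).

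By programme, all 11 measured genes of the naive, stem-like and memory list were higher with PD1_Clec9a than with PD1 (median log2 1.87, camera adjusted p = 5.83e-10, but adjusted p = 0.212 with an estimated correlation). Il7r and Slamf6 passed over all genes, and 6 members passed when adjusted over the list alone, among them the transcription factors Tcf7 (log2 1.99) and Klf2 (2.79). In the proliferation list 17 of 18 genes were lower (median log2 -1.13, camera adjusted p = 9.53e-08, but adjusted p = 0.293 with an estimated correlation). None of them passed over all genes and 6 passed when adjusted over the list alone, including Mki67, Top2a, Pcna and Stmn1. The cytotoxic effector list fell (median log2 -0.51, 12 of 18 lower, camera adjusted p = 0.0191, but adjusted p = 0.413 with an estimated correlation), with 2 members passing over all genes and 4 adjusted over the list alone. The interferon gamma response list (median log2 -0.40, 12 of 14 lower, camera adjusted p = 0.00615, but adjusted p = 0.293 with an estimated correlation) and the regulatory T list (median log2 -0.50, camera adjusted p = 0.0191, but adjusted p = 0.212 with an estimated correlation) fell too. The checkpoint and exhaustion list did not pass (camera adjusted p = 0.062). By fry, which tests whether the genes of a set move on balance one way, the naive, stem-like and memory list passed (adjusted p = 0.0419) and proliferation did not (0.133). Animal m11 stood apart in the mean log2 CPM of these lists: 8.58 for naive, stem-like and memory genes against 6.26 to 6.97 in the other 4 PD1_Clec9a animals, and 5.30 for proliferation against 6.49 to 7.18. Without m11 the first list had a median of 1.37 and proliferation one of -0.94, and both passed. The PD1 animals stood apart from PBS as well: 5.08 to 5.54 against 6.79 to 7.48 for naive, stem-like and memory genes. For proliferation the PD1 values were 7.59 to 7.66 against 5.02 to 7.45. Neither list passed for PD1_Clec9a against PBS, so a rise of naive, stem-like and memory genes over PBS was not shown. The cytotoxic effector list did not pass without m11 (-0.44) or m8 (-0.36) and the regulatory T list without m6 (-0.42), while its median was -0.33 without m11 and that of the interferon gamma response -0.24 without m12.

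Depth per cell and the stress list moved with these groups, while handling itself was not measured. The stress list was higher with PD1_Clec9a (median log2 0.89, 12 of 13 higher, camera adjusted p = 0.00416, but adjusted p = 0.708 with an estimated correlation). This list did not pass without m11 (median 0.54, camera adjusted p = 0.0803), whose mean log2 CPM was 8.90 against 6.98 to 8.18 in the other 4 animals, and its median was 0.56 without m13. A CD8 T cell held a median of 739.5 UMIs with PD1_Clec9a, 1320.5 with PD1 and 865 with PBS. The 48 calls compare with 824 genes at an unadjusted p under 0.05 and with 80 higher and 42 lower by DESeq2, which included 47 of the 48. They rested on the 3 PD1 animals: 4 genes passed without m6, 8 without m8 and 20 without m9. The count was 28 without m12, 87 without m13, 25 without m14 and 107 without m2 (PBS), while Gzmb and Il7r passed without any 1 animal. In this fit 37% of simulated 2-fold and 83% of 4-fold changes were found, with 5041 genes tested.

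**Figure D2:**
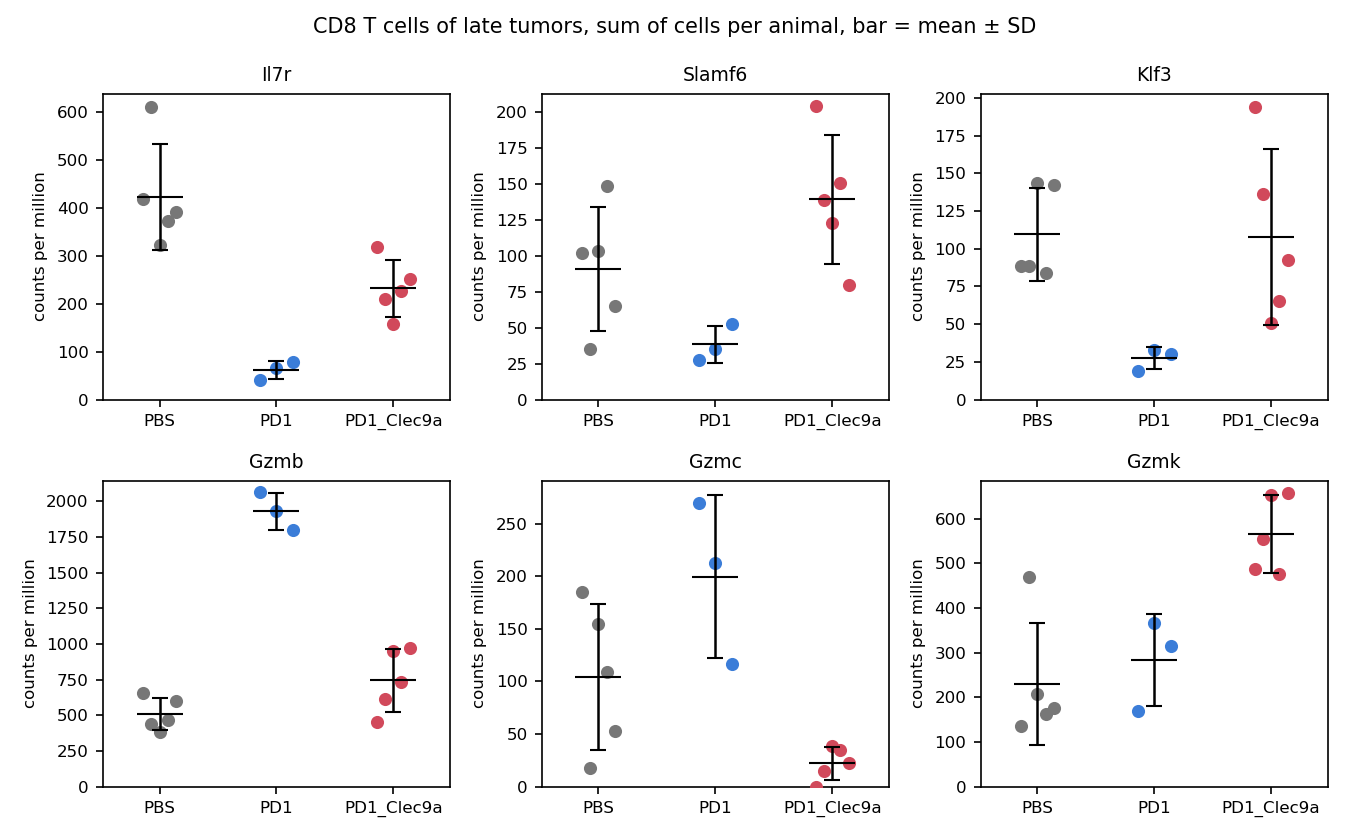
Levels (CPM) of 6 genes in the CD8 T cells of late tumors, 1 point per animal, bars for mean ± SD. Il7r averaged 232 with PD1_Clec9a and 61.8 with PD1, while Gzmb averaged 745 and 1929.

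Against PBS (5 against 5 animals), late CD8 T cells with PD1_Clec9a changed in 3 genes. Gzmk, a granzyme of early effector and memory CD8 T cells (chromosome 13, 113171608 to 113225908), rose by log2 1.39 ± 0.27 (566 ± 87.1 against 229.7 ± 136 CPM, edgeR, adjusted p = 0.0448), and Wdr95 rose by 1.89 ± 0.39 (edgeR, adjusted p = 0.0448). Ccl1, a chemokine that attracts CCR8+ cells (chromosome 11, 82176657 to 82305690), fell by 4.90 ± 0.65 (3.06 ± 2.87 against 107 ± 81.1, edgeR, adjusted p = 1.14e-04). Its few UMIs in the PD1_Clec9a animals leave the size of this fold uncertain. For each of the 3 genes the 5 animals lay apart from the other 5. Pdcd1 did not pass (log2 0.20, edgeR, adjusted p = 0.932). The count was 1 without any 1 of m12 to m15, m3 to m5 or m9, and 0 with only the 2 treatments in the fit. DESeq2 called 3 higher and 2 lower, and 343 genes had an unadjusted p under 0.05.

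The lists that rose against PBS were the type I interferon response (median log2 0.60, camera adjusted p = 0.00678, but adjusted p = 0.313 with an estimated correlation), MHC class II presentation (median log2 0.97, 5 of 5 higher, camera adjusted p = 0.00678, but adjusted p = 0.313 with an estimated correlation), the interferon gamma response (median log2 0.26, camera adjusted p = 0.0208, but adjusted p = 0.447 with an estimated correlation) and MHC class I presentation (median log2 0.26, camera adjusted p = 0.0306, but adjusted p = 0.480 with an estimated correlation). The regulatory T list fell (median log2 -0.36, camera adjusted p = 0.0159, but adjusted p = 0.298 with an estimated correlation), with the IL-2 receptor chain Il2ra at -2.06 and the transcription factor Ikzf2 at -0.67. The stress list (median log2 0.49, camera adjusted p = 0.00568, but adjusted p = 0.376 with an estimated correlation) and the T cell marker list (median log2 0.25, camera adjusted p = 0.0128, but adjusted p = 0.254 with an estimated correlation) rose beside them. The MHC class II list did not pass without m15 (median 0.32, camera adjusted p = 0.207). In m15 its mean log2 CPM was 7.58 against 5.42 to 6.56 in the other 4 PD1_Clec9a animals, and that of monocyte and macrophage markers 7.90 against 5.79 to 7.35. The type I list did not pass without m5 (0.39), the interferon gamma list without any 1 of m1, m3, m5, m13 or m15 (0.08 to 0.24), MHC class I without any 1 of m1, m3, m5, m13, m14 or m15 (0.20 to 0.26), the regulatory T list without m11 (-0.25), stress genes without m11 (0.25) or m13 (0.53), and T cell markers without m5 (0.18) or m13 (0.19).

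The PD1 antibody alone (3 animals) set against PBS (5 animals) gave 4 higher and 15 lower genes in the same late CD8 T cells. Gzmb rose by log2 1.90 ± 0.21 (edgeR, adjusted p = 3.32e-07), and so did Mir147 (2.82), the activation marker Ly6a (1.53, adjusted p = 0.00285) and the nucleic acid sensor Zbp1 (1.10, adjusted p = 0.0317). Il7r fell by 2.77 ± 0.29 from 423 ± 111 CPM (edgeR, adjusted p = 2.59e-07) and the survival gene Bcl2 fell by 1.60 ± 0.27 (edgeR, adjusted p = 0.0017). Ssh2 (log2 -2.11), Emb (-1.51), Thap3 (-1.79), Klf3 (-1.99), Clk1 (-1.41), Rgs10 (-2.45), Gm26740 (-2.35) and Ighm (-1.69) fell, as did 5730508B09Rik and the cytoskeletal regulator Rflnb (0.909 against 46.5 CPM, too near 0 for a fold). Pdcd1 did not pass (log2 0.53, edgeR, adjusted p = 0.301). This comparison uses the same 3 PD1 animals as the one between both antibodies, so opposite signs in them are not independent. DESeq2 called 13 higher and 32 lower, and 595 genes had an unadjusted p under 0.05. The count was 6 without m6 or m8, 12 without m9, 30 without m1 and 84 without m11 (PD1_Clec9a).

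In the proliferation list 18 of 18 genes were higher with PD1 than with PBS (median log2 0.76, camera adjusted p = 7.27e-08, but adjusted p = 0.247 with an estimated correlation). None of them passed over all genes. The naive, stem-like and memory list fell in 11 of 11 (median log2 -1.94, camera adjusted p = 1.40e-13, but adjusted p = 0.0794 with an estimated correlation), and 9 members passed when adjusted over the list alone against 1 over all genes. Of the interferon gamma response list 14 of 14 genes had a positive log2 value (median log2 0.59, camera adjusted p = 6.32e-07, but adjusted p = 0.0794 with an estimated correlation). Cytotoxic effector genes (median log2 0.39, camera adjusted p = 0.00121, but adjusted p = 0.247 with an estimated correlation), checkpoint and exhaustion genes (0.57, camera adjusted p = 0.00653, but adjusted p = 0.275 with an estimated correlation), type I interferon response genes (0.40, camera adjusted p = 0.00803, but adjusted p = 0.275 with an estimated correlation) and MHC class I presentation genes (0.35, camera adjusted p = 0.00757, but adjusted p = 0.275 with an estimated correlation) rose. In the checkpoint list Entpd1 (log2 1.46), Lag3 (1.05), Pdcd1 (0.53) and Eomes (-1.54) passed when adjusted over the list alone. The type I interferon list did not pass without m5 (median 0.25) or m9 (0.27) and had 0.65 without m4, and the cytotoxic effector median was 0.14 without m8.

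Late CD4 T cells other than Treg and late cDC1 gave few calls. For CD4 T cells 0 of 936 genes passed by edgeR against PD1, where m9 was the only PD1 animal and was assumed to vary like the others (58 at an unadjusted p under 0.05, 1 higher by DESeq2), and 0 passed against PBS (41 and 0). Pdcd1 gave log2 0.00 and -0.21. In cDC1 (3 animals against 2 with PD1) Txn-ps1, a thioredoxin pseudogene, fell by 1.80 ± 0.33 on the log2 scale (538 ± 129 against 1849 ± 162 CPM, edgeR, adjusted p = 0.0437). This was 1 of 1940 genes, with 186 at an unadjusted p under 0.05 and 1 lower by DESeq2. The count was 0 without m12 or m15, 3 without m14, 4 without m5, 6 without m2 or m8 and 36 without m6. Clec9a gave log2 -0.44 (edgeR, adjusted p = 0.803) and, against PBS, -0.26, where 0 genes passed by edgeR (44 at an unadjusted p under 0.05, 0 by DESeq2).

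In late cDC1 the interferon gamma response list (median log2 -0.90, camera adjusted p = 0.00602, but adjusted p = 0.523 with an estimated correlation) and the MHC class I presentation list (median log2 -0.58, camera adjusted p = 0.0156, but adjusted p = 0.523 with an estimated correlation) fell against PD1. H2-K1 (log2 -0.97), H2-D1 (-0.72) and B2m (-0.74), the chains of classical class I molecules, passed when adjusted over the class I list alone. The interferon gamma list did not pass without m12 (median -0.51) or m8 (-0.59), nor the class I list without m12 (-0.57), m6 (-0.42) or m8 (-0.54). In late cDC1 18% of simulated 2-fold and 57% of 4-fold changes were found, and in late CD4 T cells 5% and 33%.

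The make-up of the late tumor T cells was compared next. Early effector CD8 cells (EarlyEffectors) were 44.1% ± 10.2 of annotated TCRB+ cells with PD1_Clec9a, 30.4% ± 2.96 with PD1 and 20.5% ± 5.36 with PBS. Tregs were 8.60% ± 5.15, 18.6% ± 3.33 and 29% ± 13.3. Neither passed against PBS (log2 1.11 ± 0.37 and -1.74 ± 0.51, edgeR, adjusted p = 0.0578 for both) or PD1 (log2 0.53, adjusted p = 0.485, and log2 -1.10, adjusted p = 0.221). Dysfunctionals were 8.03% ± 4.54 with PD1_Clec9a, 27.4% ± 10.5 with PD1 and 10.5% ± 7.65 with PBS (log2 -1.77 against PD1, edgeR, adjusted p = 0.106). Naive_MemoryLike cells were 16.7% ± 16.1 with PD1_Clec9a, 4.57% ± 0.38 with PD1 (log2 1.87, edgeR, adjusted p = 0.0924) and 21.2% ± 10.4 with PBS. The PD1_Clec9a mean rests on m11 at 45.0%, and the other 4 animals averaged 9.67% ± 3.48. By edgeR 0 of 30 tests passed, with 6 at an unadjusted p under 0.05 and 0 by permutation. The count was 5 in cells with at least 500 UMIs, 4 without m11, m12 or m15 and 1 without m1.

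In the late CD11c+ MHCII+ gate 2 of 27 tests passed (9 at an unadjusted p under 0.05). MregDC Ccr7+, the mature dendritic cells that migrate to lymph nodes, were 4.30% ± 2.31 with PD1 against 19.4% ± 6.34 with PBS (log2 -2.17, edgeR, adjusted p = 0.0333). With PD1_Clec9a they were 8.57% ± 3.85 (log2 -1.18 against PBS, edgeR, adjusted p = 0.0721). EarlyEffectors, T cells found in this gate, were 2.49% ± 2.39 with PD1_Clec9a against 0.168% ± 0.239 with PBS (log2 3.18, edgeR, adjusted p = 0.0333), from 21 and 2 cells. The cDC1 share was 14.5% ± 5.17, 12.1% ± 4.14 and 9.35% ± 6.55 with PD1_Clec9a, PD1 and PBS, and did not pass (log2 0.22 against PD1, edgeR, adjusted p = 0.766). By permutation 0 passed. The count was 0 without m1, m6 or m9, 1 without m5, m13, m14 or m15, 4 without m4 and 8 without m11.

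The same comparison was made in the draining lymph node, where T cells are primed. Tregs were 5.79% ± 1.55 of annotated dLN TCRB+ cells with PD1_Clec9a (n = 5), 13.1% ± 0.90 with PD1 (n = 3) and 7.88% ± 1.18 with PBS (n = 5). They were lower with PD1_Clec9a than with PD1 (log2 -1.14 ± 0.20, edgeR, adjusted p = 9.0e-04, 0 of 5 animals above the PD1 mean) and higher with PD1 than with PBS (log2 0.73 ± 0.20, edgeR, adjusted p = 0.0182). Against PBS the PD1_Clec9a value did not pass (log2 -0.41, edgeR, adjusted p = 0.228). CD8 types did not pass: NaiveMem CD8 cells were 32.0%, 28.5% and 34.9% with PD1_Clec9a, PD1 and PBS, Act CD8 cells 7.20%, 5.87% and 6.41%, and Eff cells 11.2%, 10.6% and 8.29%. The Treg calls were 2 of 15 tests, with 3 at an unadjusted p under 0.05. The permutation test gave an adjusted p of 0.134 from the smallest exact p these groups allow, 0.0179. The higher share with PD1 than PBS was lost without m2, m6 or m7, and without the 1 plate whose gate label lacks a plus sign. In the dLN CD11c+ MHCII+ gate, where only T cell types were annotated, 0 of 6 tests passed by edgeR (0 at an unadjusted p under 0.05, 0 by permutation).

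**Figure D3:**
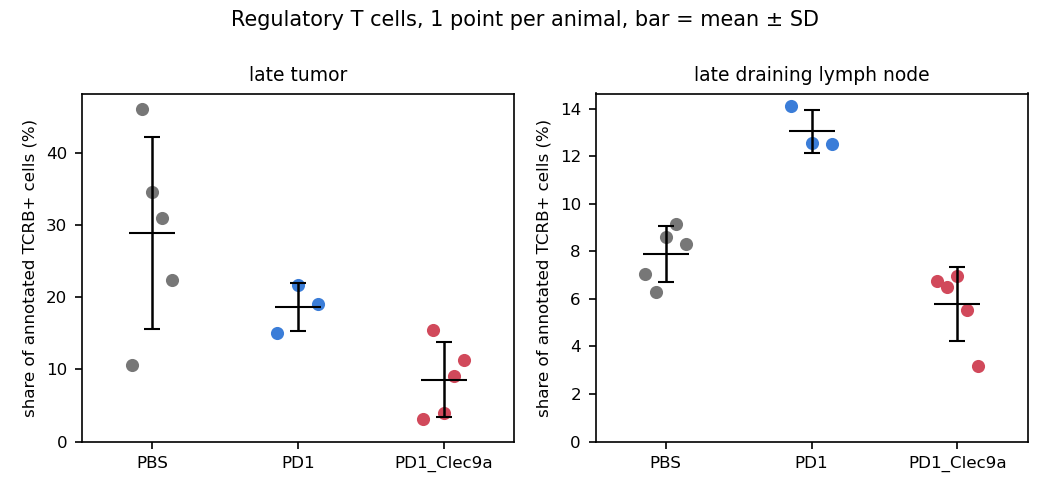
Treg share of annotated TCRB+ cells (percent) in late tumors and late draining lymph nodes, 1 point per animal, bars for mean ± SD. In the dLN the means were 5.79% with PD1_Clec9a, 13.1% with PD1 and 7.88% with PBS.

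Interferon-driven genes were lower in dLN CD8 T cells with PD1_Clec9a (5 animals) than with PD1 (3 animals). Of 5019 genes 3 fell and 0 rose. Among them were the interferon-induced GTPases Igtp (chromosome 11, 58199556 to 58207591) and Ifi47 (49076587 to 49096974). Igtp fell by log2 1.18 ± 0.23 (209 ± 74.6 against 475 ± 161 CPM, edgeR, adjusted p = 0.0105) and Ifi47 by 0.79 ± 0.17 (344 ± 41.8 against 591 ± 108 CPM, edgeR, adjusted p = 0.0435), each with 5 of 5 animals below all 3. All 13 measured genes of the interferon gamma response list were lower (median log2 -0.82, camera adjusted p = 1.24e-11, adjusted p = 0.0118 with an estimated correlation, fry adjusted p = 0.0130). Adjusted over the list alone 9 passed, among them Irgm1 (log2 -1.03), Gbp2 (-0.93) and Psmb8 (-0.36), against 2 over all genes. The type I interferon response list fell in 10 of 10 (median log2 -0.83, camera adjusted p = 3.81e-07, adjusted p = 0.0118 with an estimated correlation), with Isg15 (log2 -1.61), Irf7 (-1.18), Ifi27l2a (-0.95) and Rtp4 (-0.78) passing adjusted over the list alone and 0 over all genes. In the mean log2 CPM of these lists PD1 animal m6 (7.28 and 6.46) lay within the PD1_Clec9a range (6.62 to 7.34 and 5.58 to 6.59).

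The naive, stem-like and memory list rose (median log2 0.27, camera adjusted p = 0.0348, but adjusted p = 0.125 with an estimated correlation) and MHC class I presentation fell (median log2 -0.15, camera adjusted p = 0.0348, but adjusted p = 0.199 with an estimated correlation) in this comparison of dLN CD8 T cells. The first did not pass without any 1 of m6, m7, m8, m11, m13 or m14 (medians 0.16 to 0.32), nor the second without any 1 of m7, m8, m11, m13 or m15 (-0.17 to -0.08), and the median of the second was -0.31 without m6. The 3 single-gene calls were lost without m8 (0 genes, adjusted p = 0.980 for Igtp) and in a fit of only both antibodies (0 genes), and 5 passed without m6. DESeq2 also called 3 lower, and 217 genes had an unadjusted p under 0.05.

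Non-Treg CD4 T cells of the dLN gave the same direction. Ifi27l2a, an interferon-induced mitochondrial protein gene (chromosome 12, 103442167 to 103443680), fell by log2 0.89 ± 0.17 (814 ± 121 against 1514 ± 336 CPM, edgeR, adjusted p = 0.00592, 5 of 5 below all 3), as the 1 call among 3732 genes. The type I interferon response list fell in 7 of 7 (median log2 -1.30, camera adjusted p = 5.93e-08, adjusted p = 0.0138 with an estimated correlation, fry adjusted p = 0.00573), with 5 members passing adjusted over the list alone, among them Zbp1 (log2 -1.53), Bst2 (-1.30) and Rtp4 (-1.73). The interferon gamma response list fell in 12 of 12 (median log2 -0.72, camera adjusted p = 5.93e-08, adjusted p = 0.0149 with an estimated correlation), with 4 members passing adjusted over the list alone, among them Irgm1 (-1.28), Igtp (-0.91) and Gbp2 (-1.15). Of the MHC class I presentation list 10 of 10 genes were lower (median log2 -0.21, camera adjusted p = 0.00661, adjusted p = 0.0282 with an estimated correlation), and none of them passed over all genes. The stress list fell beside them (median log2 -0.56, 5 of 5 lower, camera adjusted p = 0.00725, but adjusted p = 0.0586 with an estimated correlation). MHC class I and stress genes did not pass without m7 (medians -0.22 and -0.46). Among the 3 PD1 animals m7 and m8 had the high type I interferon values (mean log2 CPM 7.99 and 8.09), while m6 (6.96) lay next to the PD1_Clec9a animals (6.49 to 6.89), and in the interferon gamma list m14 (7.56) lay above m6 (7.39). Both interferon lists passed whichever animal was left out, with a type I median of -0.84 without m7 and an interferon gamma median of -1.09 without m14. The Ifi27l2a call was lost without m7 (log2 -0.84) or m8 (log2 -0.78, adjusted p = 0.308), and the count was 5 without m6, 2 without m14 and 0 without m8. DESeq2 called 1 lower, and 145 genes had an unadjusted p under 0.05.

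**Figure D4:**
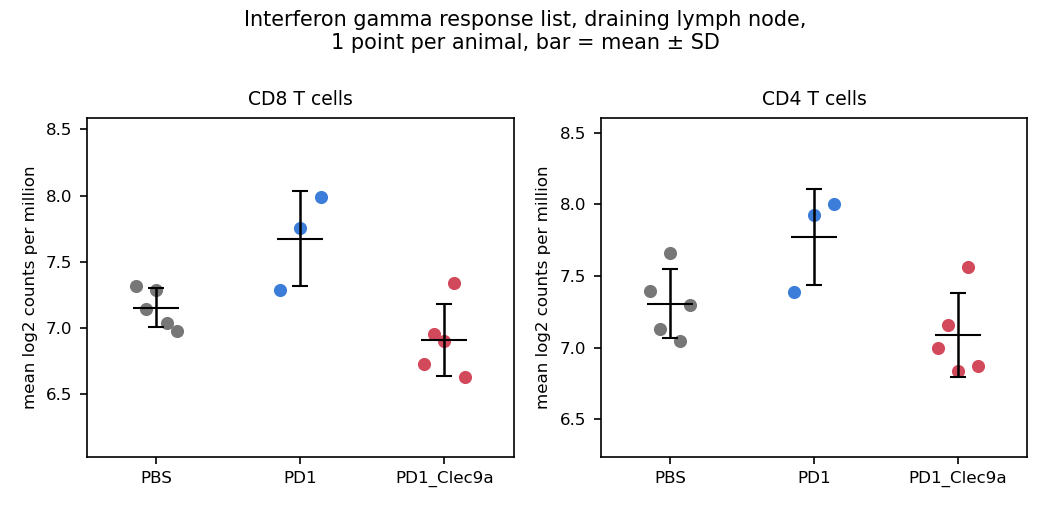
Mean log2 CPM over the interferon gamma response list in dLN CD8 and CD4 T cells, 1 point per animal, bars for mean ± SD. In CD8 T cells the means were 6.91 with PD1_Clec9a, 7.67 with PD1 and 7.15 with PBS.

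Compared with PBS, dLN CD8 T cells with PD1_Clec9a had 4 higher genes. Ctla2a, a cysteine protease inhibitor (log2 1.32 ± 0.25, edgeR, adjusted p = 0.00424), Gm8369 (1.12 ± 0.20, adjusted p = 0.00424), Txnip, a brake on glucose uptake (0.82 ± 0.17, adjusted p = 0.0193), and Klf2, the transcription factor of T cell quiescence and egress (chromosome 8, 72319033 to 72321656; 1.12 ± 0.25, 202 ± 67.8 against 93.5 ± 16 CPM, adjusted p = 0.0380), rose. No list passed (interferon gamma response camera adjusted p = 0.0549). Without the type called Eff, which carries the NK genes Ncr1 and Klrb1c, 0 genes passed, in an alternative chosen after seeing the data. The count was 2 without m1, m13, m3 or m4, 7 without m15 and 2 by DESeq2, with 305 genes at an unadjusted p under 0.05.

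With PD1 against PBS, 0 genes passed by edgeR in dLN CD8 T cells (277 at an unadjusted p under 0.05, 0 by DESeq2), or 2 without m15 and 1 without m13. The interferon gamma response (median log2 0.51, camera adjusted p = 1.36e-05, but adjusted p = 0.107 with an estimated correlation) and type I interferon response lists (median log2 0.59, camera adjusted p = 0.00161, but adjusted p = 0.107 with an estimated correlation) rose. These share the PD1 animals with the comparison between both antibodies. The type I list did not pass without m7 (median 0.28), and the interferon gamma median was 0.33 without m8. In dLN CD4 T cells against PBS 0 genes passed by edgeR (211 at an unadjusted p under 0.05, 0 by DESeq2), or 3 without m13 and 2 without m15 or m5. The type I interferon list fell there (median log2 -0.55, 7 of 7 lower, camera adjusted p = 0.00404, but adjusted p = 0.0995 with an estimated correlation) and the naive, stem-like and memory list rose (median log2 0.20, camera adjusted p = 0.0461, but adjusted p = 0.0995 with an estimated correlation). The second did not pass without any 1 of m1, m3, m5, m7, m11 or m15 (medians 0.13 to 0.20), and had 0.12 without m4.

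Whether PD1_Clec9a against PBS acted differently on CD8 T cells of the late tumor and of the dLN was tested directly over 20 units, which are the tumor and the dLN of 10 mice. By edgeR 0 of 5047 genes differed (233 at an unadjusted p under 0.05, smallest adjusted p 0.669, 0 by DESeq2), so no difference between the tissues was shown. Pdcd1 gave a difference of log2 -0.36 (edgeR, adjusted p = 0.991). The count was 3 without the tumor sample of m11.

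Plates of physically interacting cells held cells sorted as positive for both XCR1, the chemokine receptor of cDC1, and T cell markers. A single plate per sort came from the dLN after PD1_Clec9a, so no test was possible, and intervals (exact Clopper-Pearson, 95%) cover counting error only. Among double-positive wells with at least 500 UMIs, thinned to 500 UMIs, 64.2% (58.1% to 69.9%) of 268 held a T cell marker, and 0.746% (0.0905% to 2.67%, 2 wells) held a cDC1 marker. Background was 1.11% (0.304% to 2.83%) for cDC1 markers in 359 T-only wells and 9.80% (5.59% to 15.7%) for T markers in 153 XCR1-only wells, where cDC1 markers reached 39.9% (32.1% to 48.1%). The double-positive share of cDC1 markers was thus within background. Median depths were 1522, 1951 and 72.5 UMIs per sorted well, so XCR1-only wells were shallow. At such depth a cDC1 would give a small part of a pair's UMIs, and most XCR1-only wells showed no cDC1 marker after thinning. The marker share therefore cannot exclude a cDC1 in the double-positive wells. Wells with both markers were 0 of 268 after thinning, which allows up to 1.37% at that depth. Without thinning, an alternative chosen after seeing the data, 7 of 268 held both (2.61%, 1.06% to 5.31%), where the product of the single shares is 2.48%, against 1.39% of T-only wells and 7.84% of XCR1-only wells.

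The MHC class II gene H2-Ab1 stood at 609 CPM in the double-positive plate, 348 in T-only wells and 16294 in XCR1-only wells. Xcr1 itself had 12 UMIs in the double-positive plate, fewer than the 53 in T-only and 353 in XCR1-only wells. Of the other cDC1 markers, Wdfy4 had 13, 31 and 435 UMIs and Naaa 22, 48 and 671. Clec9a had 5, 0 and 111, and Cadm1 2, 2 and 255. Pdcd1 had 39, 3 and 11 UMIs, and Cd8a 532, 346 and 319, while Cd4 had 35, 240 and 20. The 10 genes with the highest ratio over both single-positive plates were Capn3 (56 UMIs against 0 in both, at least 15.8-fold higher over a floor of 3 UMIs per plate), Uhrf1 (62 against 3 T-only and 2 XCR1-only UMIs), Lin52 (58 against 3 and 0), Nt5dc2, Zscan22, Mthfd1l, Ska2 (9.36-fold), Zw10 (9.23-fold), Insm1 (8.92-fold) and Dhodh (8.31-fold), of 3437 genes with at least 50 UMIs. Their UMIs came from 4 to 14 wells each, and 1 well gave 75.9% of those of Lin52, 73.0% of Dhodh, 64.3% of Zscan22, 41.1% of Capn3, 38.7% of Uhrf1 and 30.4% of Nt5dc2. These wells held 8018 to 41986 UMIs, more than the median of 1522.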

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

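The tests of plate series, of the shares of whole lineages, and the counts over other groupings of the animals were chosen only after the results were seen. In early tumors the cDC1 share of CD45+ cells in PD1_Syn animal m23 was 1.09%, apart from the other 4 animals, of which the next was 2.85%. This was 1 such animal in 44 groups examined, and chance marks about 1 in 20 groups. In the dLN CD11c+ MHCII+ gate, wells without an annotated type held 2.01 cDC1 marker UMIs per 10000 over 3073 wells deeper than every empty well. The 44 empty wells held 0, but at most 15 UMIs each, too few to serve as a background. The same unannotated wells held 6.94 UMIs per 10000 of the B cell genes Cd79a and Cd79b, found in 483 of them, so what the cDC1 marker UMIs stand for stays open. In late tumors 990 of 6453 unannotated wells of the CD11c+ MHCII+ gate and 1078 of 6946 of the TCRB gate held over 1000 UMIs, against 0 empty wells.

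The gene differences between PD1_Clec9a and PD1 in late tumor CD8 T cells were weighed first. Depth per cell differed (medians 739.5 and 1320.5 UMIs). With each cell thinned to 500 UMIs the 34 called genes still measured kept a median change in the original direction of log2 1.09 (quartiles 0.83 and 1.5), 84.2% of the 1.30 before. This argues against the greater weight of deep cells in the sums as the whole cause. Thinning keeps each cell's expected gene proportions, so it cannot tell whether depth goes with the state of the cells. Thinning left out 285 of 1332 PD1_Clec9a cells and 51 of 504 PD1 cells, and of its 25 calls 9 were among the 48. A shift in the mix of CD8 types stays open: within EarlyEffectors alone these genes had a median of 0.60 (quartiles 0.44 and 0.85), 46.1% of that before. All 34 kept the original direction, and 0 of 2450 genes were called. Genes and directions were taken from sums that include these same cells, so the agreement in direction is partly built in. Mix and a change within types cannot be told apart from these values, and an effect of either antibody within cells may account for part of it. Plate order, which largely went with these 2 groups, was not tested. Tumor burden and the other consequences of treatment were not tested either.

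The lower interferon gamma response in dLN CD8 T cells with PD1_Clec9a than with PD1 was weighed next. The list median of log2 -0.82 was -0.89 without m14 and m15, the animals with undated plates. It was -0.88 in NaiveMem cells alone (12 of 12 genes lower). These values argue against the undated plates and the mix of types as the whole cause. Depth per cell was not weighed here. Over TCRB plates, median UMIs per annotated well were 830 to 1139.5 in PD1 animals m7 and m8. They were 715 to 878 in m6 and 659 to 994.5 in the PD1_Clec9a animals. Leaving out 1 PD1 animal at a time brought the median no nearer to 0 than -0.63 (without m8), although the single-gene calls ended there, with 0 genes passing. With 3 PD1 animals, a response to treatment is a hypothesis that these values do not exclude, and it could as well be a property of those animals, as the grouping counts for this comparison (3 of 56) allow.

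The larger CD8 T share of CD45+ cells in early PD1_Clec9a tumors was the last. The mean was above both controls in 3 of 3 plate series, which argues against plate series as the cause. Each series held only 1 or 2 animals per arm. The yield of annotated wells was 48.3% ± 13.6 with PD1_Clec9a, 46.5% ± 11.5 with PD1_Syn and 35.9% ± 4.92 with PBS. In wells with at least 1000 UMIs the CD8 T share was 34.6%, 12.1% and 15.1%, a difference of 22.5 percentage points between the antibodies, not smaller than among all wells. The difference from PBS was 13.4 points among all wells and 19.6 in these. A biological difference between the antibodies is consistent with these values as a hypothesis, found and tested on the same animals.

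Other groupings of the same animals gave the following for the late tumor CD8 T genes. Against PD1, 2 of 56 groupings gave as many as the real 48 calls, a share under 0.05 that argues against chance, but the other, which put m13 and m15 with the 3 PD1 animals, gave 67, so structure among the samples other than treatment stays open. Against PBS 2 of 100 groupings reached the real 3 (highest other 3), and for PD1 against PBS 1 of 56 reached 19 (highest other 12), shares under 0.05 as well. None of the shares given here and below were adjusted for the number of comparisons. Where the real count was 0, here and below, every grouping reaches it by construction, so that share says nothing about chance. For late CD4 T cells against PBS 100 of 100 groupings reached the real 0 (highest other 2).

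In the dLN, 3 of 56 groupings reached the real 3 calls in CD8 T cells against PD1, so chance is not excluded, and the grouping of m12, m13 and m14 with m7 and m8 gave 32, which points to structure among the samples other than treatment. Against PBS 2 of 100 reached 4 (highest other 4), a share under 0.05, and for PD1 against PBS 56 of 56 reached 0 (highest other 1). In CD4 T cells 6 of 56 reached 1 against PD1 (highest other 8, the same grouping of m12, m13, m14, m7 and m8, again structure among samples), and 100 of 100 reached 0 against PBS (highest other 5). For the interaction 100 of 100 reached 0 (highest other 3).

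In early tumors, 2 of 35 groupings reached the real 2 calls in CD8 T cells against PD1_Syn (highest other 2), so chance is not excluded. Against PBS 35 of 35 reached 0, with 34 in the grouping of m20 and m28 with m17, which points to structure among the samples, and between PD1_Syn and PBS 35 of 35 reached 0 (highest other 1). For cDC1 2 of 100 reached 2 against PD1_Syn (highest other 2), a share under 0.05, and 56 of 56 reached 0 against PBS (highest other 2). For monocytes and macrophages 100 of 100 reached 0 against PD1_Syn (highest other 2) and 100 of 100 reached 0 against PBS, where 1 grouping gave 16, again a sign of structure among the samples.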

How the results depend on the processing

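Plate series as a term, leaving out CD8 types that carry NK markers, unthinned sorted wells, animals with at least 20 annotated cells, the animal as a block and the lineage share alternatives were chosen only after the results were seen, and the other alternatives were planned. Under alternatives other than leaving out an animal, 670 values of named genes and types were compared. Of these, 618 kept their side of the threshold and, where they passed, their direction, 51 stopped passing and 1 reversed. Of the 51, 10 were permutation tests of shares, which had little room to pass after adjustment. With an animal left out 1423 stayed likewise, 229 stopped passing and 6 came to pass. The 618 and 1423 include 49 values that passed neither way and changed sign. Of the counts, 157 stayed within 1.5 times the value reported and 57 did not, or 284 and 83 with an animal left out. The cause was not tested for any change below, except that fewer animals or cells, only 2 treatments in the fit or another set of tested genes is part of how some alternatives are built. Treatments share no animals, so only the interaction of tissue and treatment could be paired. With the animal as a replicate block (10 mice) 0 of 5047 genes passed (0), with a smallest edgeR adjusted p of 0.115, and the block changed no call.

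By DESeq2 late CD8 T cells gave 122 genes against PD1, 5 against PBS and 45 for PD1 against PBS (the reported counts were 48, 3 and 19), late CD4 T cells 1 against PD1 (0), and dLN CD8 T cells 2 against PBS (4). RLE factors gave 1 in early CD8 T cells against PD1_Syn (2). T cells of the early CD45 gate gave 0 for CD8 T (2) and 0 for CD4 T (1), with Gzmb reversed to log2 1.48. Without a filter on low counts the counts were 4 for early CD8 T (2) and 0 for early CD4 T cells (1) against PD1_Syn, 7 for early cDC1 against PD1_Syn (2), 4 and 2 for monocytes and macrophages against PD1_Syn and PBS (0 and 0), 133 for late CD8 T against PD1 (48), 53 for PD1 against PBS (19), 8 for late cDC1 against PD1 (1), 2 for dLN CD8 T, PD1 against PBS (0), 4 for dLN CD4 T against PD1 (1) and 4 against PBS (0), and 4 for the interaction (0). At least 10 cells per animal gave 1 in early cDC1 (2), 1 in late CD4 T against PD1 (0) and 0 in late cDC1 against PD1 (1), and at least 50 cells gave 1 in early CD8 T against PD1_Syn (2). Cells with at least 500 UMIs gave 1 in early CD8 T against PD1_Syn (2), 2 in late cDC1 against PD1 (1) and 5 late TCRB shares (0). With only the 2 treatments compared the counts were 1 for early CD8 T against PBS (0), 4 for early cDC1 against PD1_Syn (2), 0 for late CD8 T against PBS (3), 76 for PD1 against PBS (19), 2 for late cDC1 against PD1 (1), 0 for dLN CD8 T against PD1 (3) and 2 for PD1 against PBS (0). The plate as the unit gave 1 and 6 in monocytes and macrophages (0 and 0), 216, 9 and 96 in late CD8 T (48, 3 and 19), 6 and 10 in dLN CD8 T against PD1 and PBS (3 and 4), 3 and 2 in dLN CD4 T (1 and 0), and 17 early CD45, 6 late TCRB and 10 late CD11c+ MHCII+ shares (6, 0 and 2). Plates of the same animal are not independent, so these plate counts do not rest on the spread between animals. TMM scaling of cell numbers gave 2 early CD45 shares (6) and 1 early TCRB share (0). Permutation gave 0 in the early CD45 (6), late CD11c+ MHCII+ (2) and dLN TCRB (2) gates. Group sizes left it little room to pass after adjustment. Plate series as a term gave 1 early TCRB share (0). Without the CD8 type that carries NK markers dLN CD8 T cells gave 0 genes against PBS (4). Without the dLN plate lacking the plus sign dLN CD4 T cells gave 1 gene against PBS (0) and the dLN TCRB gate 1 share (2). An estimated correlation left 5 of 33 list calls. Wells not thinned held cDC1 markers in 2.99% (0.746%).

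With each animal left out in turn, counts ranged from 1 to 2 in early CD8 T against PD1_Syn (2), 0 to 2 against PBS (0), 0 to 3 in early CD4 T (1), 2 to 4 in early cDC1 against PD1_Syn (2), 4 to 107 in late CD8 T against PD1 (48), 1 to 3 against PBS (3), 6 to 84 for PD1 against PBS (19), 0 to 36 in late cDC1 against PD1 (1), 0 to 5 in dLN CD8 T against PD1 (3), 2 to 7 against PBS (4), 0 to 2 for PD1 against PBS (0), 0 to 5 in dLN CD4 T against PD1 (1), 0 to 3 against PBS (0) and 0 to 3 for the interaction (0). Shares ranged from 0 to 10 in the early CD45 gate (6), 0 to 4 in late TCRB (0), 0 to 8 in late CD11c+ MHCII+ (2) and 1 to 2 in dLN TCRB (2), and list calls from 30 to 39 (33). Counts stayed 0 in early CD8 T for PD1_Syn against PBS, early cDC1 against PBS, monocytes and macrophages, late CD4 T, late cDC1 against PBS, and shares of the early TCRB, early CD11c+ MHCII+ and dLN CD11c+ MHCII+ gates. Not run, for lack of animals, were at least 50 cells in early CD4 T, early cDC1, late CD4 T and late cDC1, the plate as the unit in late CD4 T and late cDC1 against PD1, at least 500 UMIs in late CD4 T against PD1, and leaving out the lone animals m28 (early CD4 T) and m9 (late CD4 T). The list total keeps the reported value for comparisons that an alternative does not cover.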

Other observations

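The comparisons named for single lists below follow the plan, while the unthinned values of sorted wells and the Treg lineage tests were chosen only after the results were seen. Several fixed gene groups did not pass in any comparison. The Th1 list passed in 0 of 12 camera tests (smallest adjusted p 0.265) and the dendritic cell maturation list, which holds genes of migrating mature dendritic cells, in 0 of 8 (smallest adjusted p 0.104). Interferon gamma response genes passed in 7 of 20 tests, type I interferon response genes in 6 of 17, MHC class I presentation in 5 of 20, proliferation in 4 of 16, naive, stem-like and memory genes in 4 of 8, cytotoxic effector genes in 2 of 18, regulatory T genes in 2 of 11, MHC class II presentation in 2 of 9, and checkpoint and exhaustion genes in 1 of 11.

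Markers of cell types and the stress list passed in 7 of 52 tests: stress genes in 5 of 20, T cell markers in 1 of 14 and cDC2 markers in 1 of 2. Monocyte and macrophage markers (7 tests), cDC1 markers (6 tests) and NK markers (3 tests) passed in 0. Neutrophil, B cell, plasmacytoid DC, melanoma, erythroid and mast cell lists never had 4 tested genes.

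Tregs as a lineage gave 8.60% with PD1_Clec9a, 18.6% with PD1 and 29% with PBS in the late tumor T cell gate (exact two-sided permutation p = 0.0536 against PD1 and 0.0238 against PBS, 0.190 for both after adjustment over 9 tests). In the dLN the lineage gave an exact permutation p of 0.0179 against PD1, adjusted 0.0536. The change in the tumor was not tested against that in the dLN.

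Sorted double-positive wells that were not thinned held a cDC1 marker in 2.99% of cases, against 1.67% of T-only and 59.5% of XCR1-only wells.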
